A study of Mus musculus with 8 samples.

How the data were processed

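RNA pulled down with tagged ribosomes was measured by RNA sequencing in 8 hippocampal libraries, none of which holds RNA from before the pull-down. Translating ribosome affinity purification (TRAP) pulls down ribosomes that carry a tag, here the ribosomal protein L10 fused to EGFP, which Cre recombinase switches on in cells that express or once expressed Cck. The 3 wild-type (WT) libraries came from littermates without the homozygous floxed allele, and the 5 conditional knockout (cKO) libraries came from mice with both floxed copies of Hltf, the gene that encodes SMARCA3. Per the labels, each library pools 4 hippocampi, and nothing else is stated on how the pools relate to each other. The p-values therefore measure the spread between these 8 pools.

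The deposited table holds raw counts, whole numbers without scaling, for 39017 Ensembl genes in all 8 libraries. The authors' processing notes name STAR 2.5.3a for alignment, HTSeq for counting and the genome build mm10. They do not state the annotation release, the strandedness of the counting or any filter. Gene symbols, positions, GC content and transcript length were taken from GENCODE vM21 for the same build. A symbol was matched for 37607 genes (96.4%), and the 1410 genes without one took 0.616 to 0.651% of the counts of a library. GC content was known for 98.2% of the genes tested.

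Total counts ran from 31760155 to 61823651 per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16: trimmed-mean (TMM) scaling, filterByExpr by group, a quasi-likelihood fit with robust dispersions and a two-sided test of cKO against WT. Adjusted p-values are Benjamini-Hochberg values over the 17654 genes tested, and a gene was called at an adjusted p under 0.05. Expression is given in CPM, the library-scaled count unit of edgeR, with TMM-scaled totals. DESeq2 gave an adjusted p for 11362 genes. Counts were simulated for each gene independently, with its fitted dispersion in all libraries, and only genes with a mean CPM of at least 1 were changed. The 8-library test recovered 4, 25, 34 and 44 of 50 genes changed by a factor of 1.5, 2, 3 and 4, with 2 false calls among 17052 unchanged genes tested. The 6-library test recovered 21, 33, 41 and 48 of 50, with 5 false calls among 16831. Spread shared across genes or larger in some libraries was not simulated, so these rates may not hold for the real data.

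A set of 41 gene lists with 890 genes, of which 821 were tested, covered cell types, neighbouring regions, complexes and pathways. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Beside it stand camera with a correlation estimated for each list, the fry test, and counts of members with p-values adjusted over the list alone. The lists, the groups, the test, most of the other settings and the rule for named genes were fixed before the data were examined. The rule names Hltf and the proteins of its complex, Cck and Rpl10a; genes past the threshold; where fewer than 5 pass in a direction, the 8 genes with the smallest p in that direction with a mean CPM of at least 1 and no overlap between groups, predicted genes left out; and up to 4 members with the smallest p from each list described. Some genes that the rule names are not reported here.

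Single values were compared by exact permutation tests, two-sided, over the 56 splits of 8 libraries into 3 and 5, for which the smallest possible p is 0.0179. Exact tests of list means and library measures were chosen after seeing the data. Genes within 10 Mb of Hltf were compared with all others by Fisher's exact test, two-sided. Alternatives were other scalings, other filters on low counts, non-robust dispersions, each library left out, 6 libraries with numbers present in both groups, with and without that number in the model, a covariate from markers of astrocytes, oligodendrocytes, their precursors, microglia and vessels, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom with quality weights, an adjusted p under 0.1 and a test against a 1.2-fold change. A correction that removes each library's trend of log2 CPM on GC content and transcript length was added after seeing the data. Reads shared between genes cannot be reassigned from a count table, and 74 of the genes tested have the same counts as another gene in every library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.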

Results

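The data are counts of RNA from TRAP pull-downs of hippocampal CCK cells in 3 WT and 5 cKO libraries, each from 4 pooled hippocampi. Total counts were 37239119, 49522676 and 47670751 in WT 1, 2 and 3. They were 51637772, 61823651, 31760155 and 47461371 in cKO 1, 2, 3 and 4 and 38776329 in the library labelled cKO 5, whose Hltf level goes against its label. The exact permutation test of library totals between the groups gave a p of 0.839. In the principal components of log2 CPM, the library labelled cKO 5 stood apart on the first component (31.1% of variance) and cKO 4 on the second (22.3%). Genes without a count despite a mean CPM of at least 1 elsewhere numbered 75 in the library labelled cKO 5, 25 in cKO 4 and 4 to 19 in the other libraries.

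**Figure D1:**
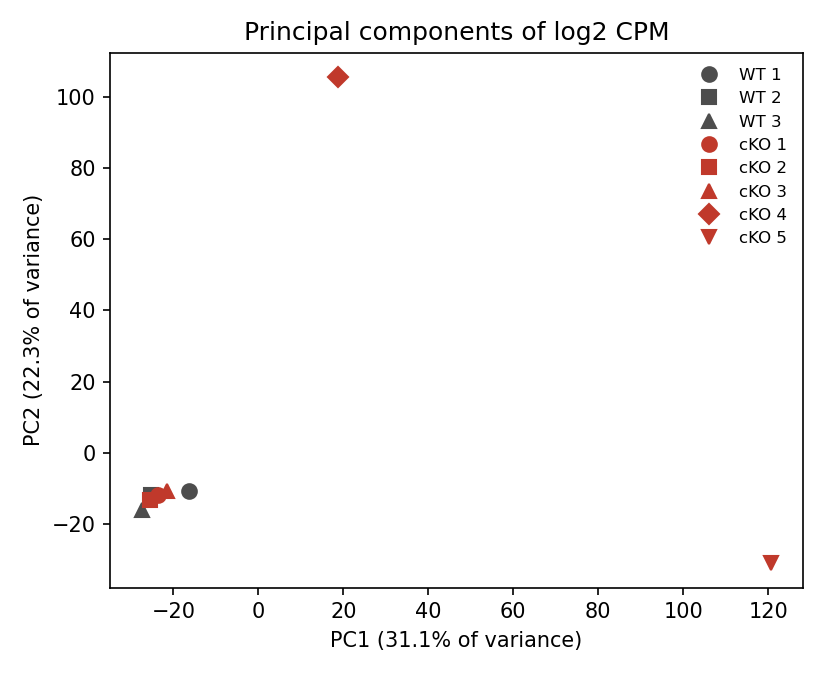
Each point is 1 library on the first (31.1% of variance) and second (22.3%) principal components of log2 CPM, with WT and cKO in different colours. The library labelled cKO 5 lies at 120.7 on the first component and cKO 4 at 105.5 on the second, away from the other 6 libraries.

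The comparison of cKO with WT asks which RNAs in pull-downs from CCK cells differ when SMARCA3, a chromatin remodeller of the SWI/SNF family, is deleted. Hltf (ENSMUSG00000002428, mm10 chromosome 3, 20057811 to 20118490) was at 13.7, 8.39 and 9.87 CPM in WT 1, 2 and 3, from 515, 421 and 479 counts. It was at 5.10, 4.49, 4.21 and 2.83 CPM in cKO 1, 2, 3 and 4, from 266, 281, 135 and 131 counts. The library labelled cKO 5 had 11.4 CPM, from 421 counts, within the WT range. Means were 10.7 ± 2.74 CPM (SD, n = 3) in WT and 5.61 ± 3.36 CPM (SD, n = 5) in cKO. The log2 fold change was -0.93 (SE 0.39), with an adjusted p of 0.558 by edgeR and Benjamini-Hochberg and a p of 0.107 by the exact permutation test, so the difference did not pass. Without the library labelled cKO 5 the log2 fold change was -1.36 with an unadjusted edgeR p of 3.4e-04 and an adjusted p of 0.359. Which exons are floxed is not stated, and counts per gene do not separate exons.

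Nrsn2, which encodes neurensin-2, a neuronal vesicle membrane protein, had the smallest p of all genes. Nrsn2 (ENSMUSG00000059361, chromosome 2, 152368755 to 152376638) was at 109 ± 17.6 CPM in WT (SD, n = 3) and 308 ± 69.5 CPM in cKO (SD, n = 5), and all 5 cKO libraries, the library labelled cKO 5 included, lay above all 3 WT libraries. The fold was 2.82 (log2 1.5, SE 0.18), and its edgeR adjusted p of 0.0880 missed the threshold. The exact permutation p was 0.0179, the smallest these libraries allow. Nrsn2 passed by DESeq2 (adjusted p 4.0e-11) and limma-voom (0.00192), and over all alternatives its adjusted p ran from 4.0e-11 to 0.831, the latter in edgeR without WT 2. Nrsn2 was placed on the list of the SMARCA3 and p11 complex from knowledge of the study, so its direction is not independent evidence. Gm14164, a predicted gene that overlaps Nrsn2 on the opposite strand and was named after its values were seen, had a log2 fold change of 2.02 (SE 0.27) with the same adjusted p. Within 10 Mb of Nrsn2, 31 of 215 other genes had an unadjusted p under 0.05, 14.4% against 8.68% elsewhere.

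Among the other 7 higher genes named by the rule, Syp, which encodes the synaptic vesicle protein synaptophysin (ENSMUSG00000031144, chromosome X, 7638471 to 7653256), was at 289 ± 24.4 CPM in WT (SD, n = 3) and 524 ± 94.4 CPM in cKO (SD, n = 5). Its log2 fold change was 0.86 (SE 0.14), with an edgeR adjusted p of 0.446. Eif6, a factor that binds the large ribosomal subunit, had a log2 fold change of 1.01 (SE 0.17) and an adjusted p of 0.446 by edgeR. Eif6 (chromosome 2, 155819832 to 155826925) lies within 10 Mb of Nrsn2, so the 2 genes may not be separate findings. Slc17a7, a vesicular glutamate transporter, was at 0.49 (SE 0.10), and Caskin1, Gna11, Grina and Phyhip lay between 0.42 and 0.77. The 8 lower genes were Rpl12, Rps27a and Rpl27a, which encode ribosomal proteins, Naca, a subunit of the nascent polypeptide-associated complex, Hmgcs1, an enzyme of cholesterol synthesis, and Basp1, Nkiras1 and Chchd2. Their log2 fold changes lay between -0.57 for Rps27a and -0.35 for Basp1. For these 8 and for Caskin1, Gna11, Grina, Slc17a7 and Phyhip the edgeR adjusted p was 0.470, so none passed by edgeR. DESeq2 called all 15 of these genes, with adjusted p between 4.1e-05 for Eif6 and 0.0113 for Chchd2. The genes were picked by their edgeR p and group separation in the same counts, so these calls are not separate evidence. edgeR called none of the 15 either without or with the GC and length correction. DESeq2 was not run with that correction.

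**Figure D2:**
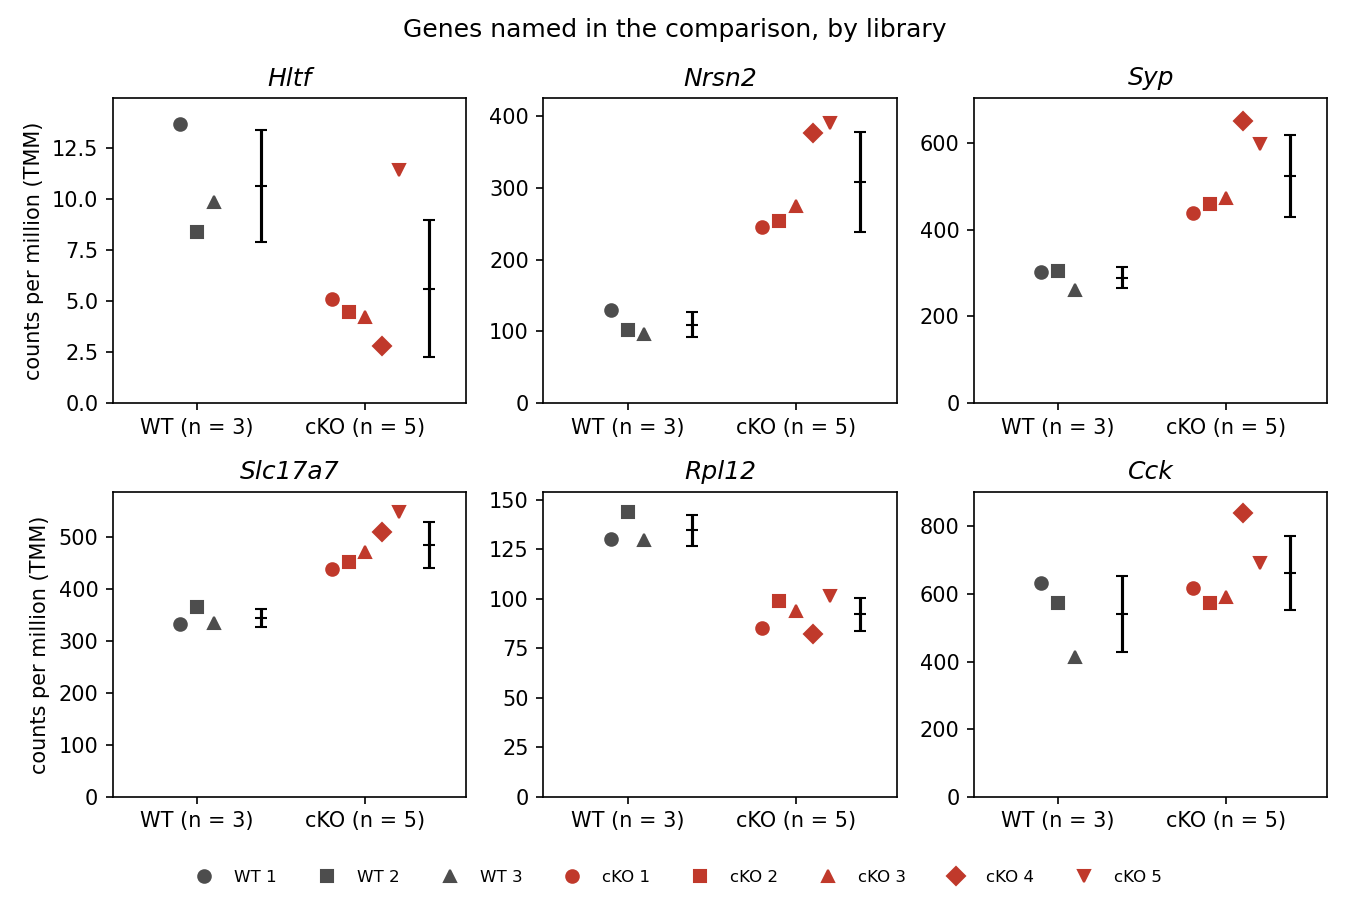
CPM of 6 genes on linear axes from 0, with 1 point per library in WT (n = 3) and cKO (n = 5) and the group mean with its SD beside them. Nrsn2, Syp and Slc17a7 lie higher in every cKO library than in any WT library and Rpl12 lies lower, while the library labelled cKO 5 has Hltf at 11.4 CPM, inside the WT range.

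Of 17654 genes tested with edgeR at an adjusted p under 0.05, 0 were higher and 0 lower in cKO. At an unadjusted p under 0.05 there were 1540, 886 higher and 654 lower, against 882.7 that chance gives. DESeq2 called 77 higher and 48 lower, and limma-voom with quality weights called 3 higher and 1 lower. The groups did not overlap in 1270 genes (596 higher, 674 lower), 7.19% of those tested against the 3.57% that chance gives. Over the 6 libraries without cKO 4 and the library labelled cKO 5, a set chosen in advance because its library numbers occur in both groups, edgeR called 5 genes higher and 5 lower. With that number in the model it called 0 higher and 0 lower. The common dispersion was 0.142 over 8 libraries and 0.0701 over these 6.

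The 15 mitochondrially encoded genes ranked higher in cKO, with a median log2 fold change of 0.59. The tagged protein, L10, belongs to cytosolic ribosomes, so counts of these genes are not evidence of RNA on tagged ribosomes of CCK cells. No library of RNA from before the pull-down is there to measure background RNA. Adjusted over the list alone, 8 of 15 rose, among them mt-Rnr1 (1.37, SE 0.33), mt-Co1 (0.81, SE 0.23), mt-Nd1 (0.75, SE 0.21) and mt-Cytb (0.80, SE 0.22); over all genes tested 0 did. The camera adjusted p was 1.6e-06 at the preset correlation, and the adjusted p = 0.75 with an estimated correlation. The share of counts from these genes was 0.158 ± 0.0191% in WT (SD, n = 3) and 0.326 ± 0.150% in cKO (SD, n = 5), with an exact p of 0.125. It was 0.213% in cKO 4 and 0.168% in the library labelled cKO 5, the lowest of the cKO libraries, and the exact p of the list means was 0.107.

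The 15 oligodendrocyte markers ranked higher in cKO, with a median of 0.78, and the mean of the list lay higher in all 5 cKO libraries than in any WT library. Mobp had a log2 fold change of 1.07 (SE 0.36) and Ugt8a 1.27 (SE 0.56), and 3 members had an unadjusted p under 0.05, all higher; 0 members passed adjusted over the list alone and 0 over all genes. Mobp, which encodes a myelin protein, was at 4.14 CPM in WT. The camera adjusted p was 0.00199 and the adjusted p = 0.299 with an estimated correlation, while the exact p of the list means was 0.0179, or 0.244 after Benjamini-Hochberg adjustment over 41 lists. Markers of astrocytes (median 0.12, camera adjusted p 0.412), oligodendrocyte precursors (0.59, 0.336), microglia (-0.09, 0.613) and vessels (0.07, 0.936) were not called. Over the 6 libraries without cKO 4 and the library labelled cKO 5 the precursor list was called (median 0.75, camera adjusted p 0.0255; 0.515 with an estimated correlation). The 10 choroid plexus and ependymal markers also lay higher, with a median of 0.56, 9 of 10 above 0 and a camera adjusted p of 0.0694, and 4 of 5 cKO libraries, cKO 2 excepted, lay above all WT libraries. That list was called without WT 2 (0.0262), WT 3 (0.0142) or cKO 2 (0.00621), while the adjusted p = 0.75 with an estimated correlation. For microglia and vessels the mean (0.05 and 0.13) and the downward test differ in sign, and for vessels the median does too. The microglia list lay at -1.32 in cKO 4 and -1.25 in the library labelled cKO 5 on the log2 scale against the WT mean, and at -0.59 in WT 1. Its 4 members with the smallest p had a mean of 0.39 to 0.51 CPM over all 8 libraries, near the floor.

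The 31 glutamate receptor genes ranked higher in cKO, with a median of 0.11. Grik5 had a log2 fold change of 0.65 (SE 0.18) and Grin1 0.68 (SE 0.21), and 7 members had an unadjusted p under 0.05, all higher; adjusted over the list alone 0 passed, as over all genes. The camera adjusted p was 0.0423 and the adjusted p = 0.373 with an estimated correlation, and the call ended without WT 1 (0.0637), WT 2 (0.105) or cKO 1 (0.158) and after the GC and length correction (0.258). The list mean was higher in all 5 cKO libraries than in any WT library (exact p 0.0179, or 0.244 after Benjamini-Hochberg adjustment over 41 lists), and fry gave an adjusted p of 0.0155.

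The 78 cytosolic ribosomal protein genes ranked lower in cKO, with a median of -0.16. Adjusted over the list alone 4 fell, Rps27a, Rpl4, Rpl12 and Rpl27a, while 0 passed over all genes and 20 had an unadjusted p under 0.05, all lower. The camera adjusted p was 2.9e-05 and the adjusted p = 0.75 with an estimated correlation; without cKO 1 the camera adjusted p was 0.119, and the exact p of the list means was 0.214. The 76 oxidative phosphorylation genes encoded in the nucleus had a median of -0.06, with 15 lower and 3 higher at an unadjusted p under 0.05. Ndufa6 (-0.40), Cox6c (-0.39) and Uqcrb (-0.38) were among the lower and Atp5g1 (0.31) among the higher; adjusted over the list alone 0 passed, as over all genes. The camera adjusted p was 0.0230 and the adjusted p = 0.75 with an estimated correlation. That call ended without WT 1 (0.165), WT 2 (0.155) or cKO 1 (0.269) and after the GC and length correction (0.258), and the exact p of the list means was 0.161. With the non-neuronal covariate in the model, the mitochondrial, glutamate receptor, ribosomal and oxidative phosphorylation lists were not called. The oligodendrocyte list is part of that covariate, so the loss of its call there is built in. Across 7548 genes with a mean log2 CPM above 4, the fold change had a Spearman correlation of 0.321 with GC content and 0.200 with transcript length; genes are not independent replicates.

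**Figure D3:**
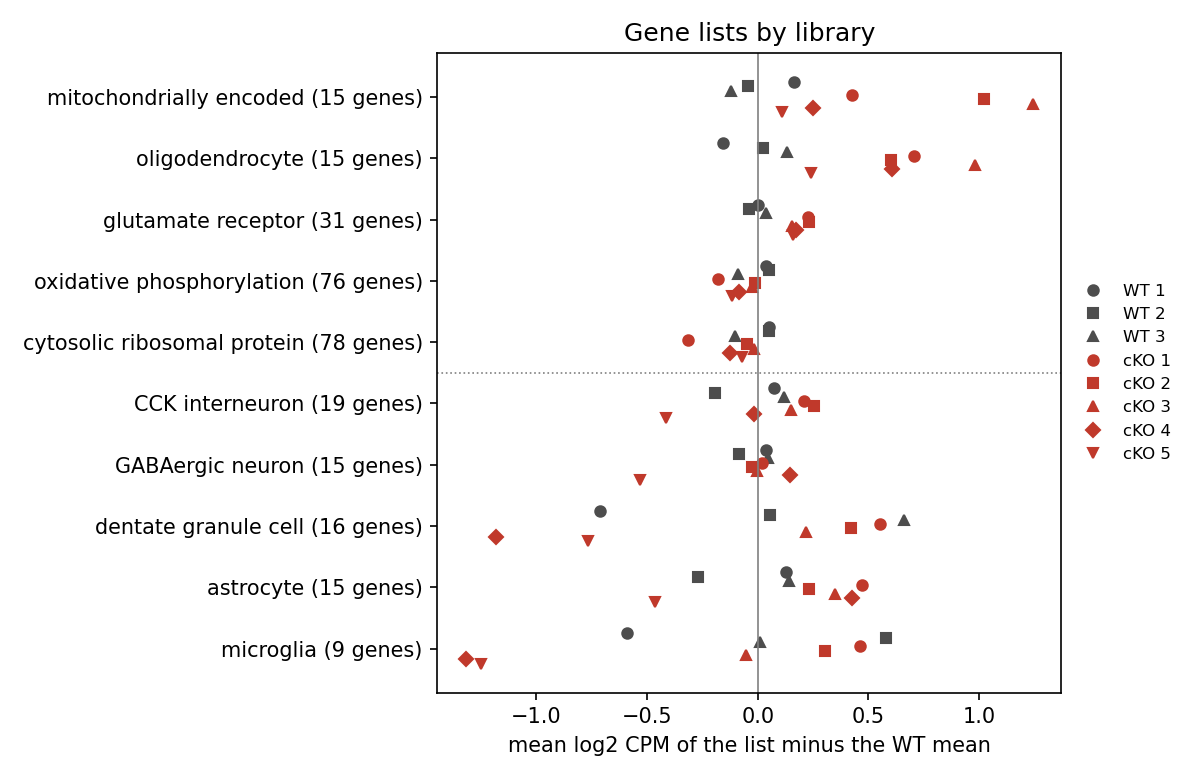
Mean log2 CPM of 10 gene lists in each library, minus the WT mean, with 1 point per library; the 5 lists above the dotted line are those called by camera at the preset correlation. The oligodendrocyte and glutamate receptor lists lie higher in every cKO library than in any WT library. The microglia list lies at -1.32 in cKO 4, -1.25 in the library labelled cKO 5 and -0.59 in WT 1.

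The lists of CCK interneuron, GABAergic and glutamatergic neurons were not called by camera. Of the glutamatergic list (19 tested; median 0.09, camera adjusted p 0.412), 5 members were higher and 1 lower at an unadjusted p under 0.05, and Slc17a7 (0.49) and Cpne6 (0.36) rose adjusted over the list alone. The CCK interneuron list (19 tested) had a median of 0.16 and a camera adjusted p of 0.646, with 0 members at an unadjusted p under 0.05. Cck itself was at 540 ± 112 CPM in WT (SD, n = 3) and 661 ± 108 CPM in cKO (SD, n = 5), with an exact p of 0.214. The GABAergic list (15 tested) had a median of 0.04 and a mean of 0.0023 while its test pointed down, at a camera adjusted p of 0.646. Rpl10a, which encodes a ribosomal protein often tagged for TRAP, had a log2 fold change of 0.02 (SE 0.09) and an edgeR adjusted p of 0.967.

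Of the list of the SMARCA3 and p11 complex, 4 members were tested, with a median of -0.15, a mean of 0.07 and an upward test at a camera adjusted p of 0.798. S100a10, which encodes p11, had a fitted log2 fold change of 0.06 (SE 0.37), while the difference of its mean log2 CPM was -0.056, with an exact p of 0.929. Ahnak was at -0.36 (SE 0.74), with an adjusted p of 0.928 by edgeR, and Anxa2, at 0 to 12 counts per library, was not tested. Adjusted over the list alone, Nrsn2 rose. It was placed on the list from knowledge of the study, so this pass is not independent evidence, and the list mean includes it.

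Within 10 Mb of Hltf, 44 genes were tested and 0 were called by edgeR. At an unadjusted p under 0.05 there were 2 (4.55%, against 8.76% elsewhere), with an odds ratio of 0.50 (95% interval 0.0581 to 1.91) and a Fisher's exact p of 0.431.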

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

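The tests of Hltf in the library labelled cKO 5 were chosen only after its level had been seen, and the bound by which the position of that library is read was made stricter after the position was known. Of 67 tests for a cKO library far from the other 4, 6 passed, where chance alone gives about 3.35.

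Hltf in the library labelled cKO 5 lay at 11.4 CPM while the other cKO libraries lay at 2.83 to 5.10, a gap of 0.737 of the whole range. Of 4018 genes of similar CPM, 7.07% deviate there from the other cKO libraries by as much as Hltf does (1.48 on the log2 scale). The median absolute deviation of these genes was 0.444. Low complexity of that library thus stays possible, but the share was not taken in other libraries and cannot tie the Hltf level to it. A WT sample under a cKO label was tested on 39 genes chosen without that library, on a scale with the WT mean at 0 and the mean of the other cKO libraries at 1. The library had a median position of 1.22, closer to cKO at 26 of the 39 genes, but the 95% interval of 0.40 to 1.33 reaches below 0.5. That interval covers genes within this library, which are not independent replicates, and does not measure the spread between samples. Single genes there lie on both sides, Nrsn2 at 390 CPM (WT 96.8 to 129) and Syp at 598 (WT 261 to 306) with the cKO libraries and Rpa3 at 24.0 (WT 17.3 to 22.9) with WT, so a wrong label cannot be told apart from a cKO sample with incomplete deletion, which was not tested.

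Chchd2 in cKO 1 was at 573 CPM, against 424 to 445 in the other cKO libraries, a gap of 0.863 of the range. The GABAergic list lay at -0.53 on the log2 scale against the WT mean in the library labelled cKO 5, a gap of 0.749. The astrocyte list lay at -0.47 there, a gap of 0.741. The meningeal fibroblast list lay at -1.79 there, a gap of 0.738, and was not called (camera adjusted p 0.708). The potassium channel list lay at 0.03 in cKO 4, a gap of 0.733, against 0.11 to 0.14 in the other cKO libraries, and was not called (camera adjusted p 0.0837). On the scale from WT to cKO, each library placed with genes chosen without it, the median positions of cKO 1, 2, 3 and 4 were 0.33, 0.69, 0.74 and 1.24, and those of WT 1, 2 and 3 were 0.24, 0.24 and 0.52.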

How the results depend on the processing

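The GC and length correction and the count near Hltf at an unadjusted p were chosen after seeing the data. Of 28 alternatives, each of those run on Hltf kept its direction, from -1.36 to -0.70 with 1 library left out and -0.52 with the non-neuronal covariate. Of 420 comparisons of single named genes, 376 kept direction and side of the threshold, 36 came to pass and 8 reversed. Of 105 for single lists, 79 kept their call and 26 lost it, 7 of these with a library left out. Of 91 for counts and Hltf, 69 stayed and 22 moved.

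Genes called higher and lower numbered 2 and 0 without a filter, with a CPM of at least 1 in 3 libraries, with 1 surrogate variable and at an adjusted p under 0.1; 1 and 0 after the GC and length correction; 5 and 5 over 6 libraries, and 5 and 2 there with the correction; 178 and 48 with the covariate; 77 and 48 by DESeq2; and 3 and 1 by limma-voom. They were 0 and 0 with each library left out, other scalings, non-robust dispersions and the test against a 1.2-fold change. With the replicate number as a block over 6 libraries they were 0 and 0, with 1417 at an unadjusted p under 0.05. Across genes, deviations from the group mean had r of -0.015, 0.010 and -0.040 between WT and cKO libraries of the same number, which gives no sign that the numbers pair them. Camera called 2 lists without cKO 1, 8 without cKO 2 and 2 with the covariate. It called 7 over 6 libraries, oligodendrocyte precursors (0.0255) and axon guidance (0.0318) among them, 5 there with the block and 3 with the correction. With an estimated correlation camera called 0 over 8 libraries and 0 over 6 (axon guidance 0.841), and fry called 1 over 8. Near Hltf 2 genes had an unadjusted p under 0.05. The cause of these shifts was not tested.

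S100a10 reversed without WT 1 (-0.00064), cKO 1 (-0.00074), cKO 2 (-0.011) or cKO 3 (-0.11), in a range of -0.11 to 0.25 with 1 library left out, and with the covariate (-0.73); over 6 libraries it was 0.41. Ahnak reversed without WT 1 (0.19), in a range of -0.97 to 0.19 with 1 left out. Rpl10a reversed without WT 3 (-0.038), in such a range of -0.038 to 0.069, and with the covariate (-0.00013). Anxa2, at 0 to 12 counts per library, was too low to test.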

Other observations

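The tests around Nrsn2, of oligodendrocyte against other non-neuronal markers, and of the Gapdh-related genes were chosen only after the results were seen, as was the GC and length correction, and the bounds for the mitochondrially encoded and oligodendrocyte lists were made stricter after their values were known.

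Over the 6 libraries without cKO 4 and the library labelled cKO 5, edgeR with Benjamini-Hochberg adjustment called 10 genes, all named after their values were seen except Nrsn2, Syp and mt-Rnr1. With the replicate number as a block edgeR called 0 there, with Nrsn2 at an adjusted p of 0.0598. Casp1, which encodes an inflammatory caspase, fell from 6.27 ± 0.373 to 1.28 ± 0.193 CPM (SD, n = 3 each; log2 fold change -2.30, adjusted p 0.0193). Rsrp1 (-1.17), Rpa3 (-1.45), a subunit of replication protein A, and Tmem254a and Tmem254b (-1.16, with identical counts) also fell, with adjusted p between 0.0193 and 0.0490 by edgeR. The mitochondrial ribosomal RNAs mt-Rnr1 (1.71) and mt-Rnr2 (1.62), Gm14164 (1.74), Syp (0.65) and Nrsn2 (1.24) rose, with adjusted p between 0.00741 and 0.0418 by edgeR. In the library labelled cKO 5, Rpa3 was at 24.0 and Tmem254a at 47.7 CPM, near the WT means of 20.6 and 47.3, while cKO 4 had 9.20 and 16.4. Rsrp1 was at 28.4 CPM in cKO 4 and 24.0 in the library labelled cKO 5, against 30.1 to 35.9 in WT and 13.8 to 14.8 in the other cKO libraries, and mt-Rnr2 in the library labelled cKO 5 was at 651, within the WT range of 535 to 695. Of the 125 genes DESeq2 called over 8 libraries, 3 were among these 10.

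Camera adjusted p-values of the lists not called ran from 0.0694 to 0.984. Median, mean and test differed in sign for the lists of PV and SST interneurons, thalamus, neuropeptides, GABA receptors, glucocorticoid response and interferon response. The mean of the DNA damage tolerance list lay lower in all 5 cKO libraries than in any WT library (exact p 0.0357, adjusted 0.293; camera adjusted p 0.284), in cKO 3 only just (-0.0301, against -0.0294 in WT 1). Its median was -0.0034, with 14 genes higher and 16 lower, Pcna (-0.36) and Ung (-1.03) among the latter. The nuclear-retained RNA list lay higher in all 5 (exact p 0.0179, adjusted 0.244; camera adjusted p 0.125), with Gm26917 at 1.78. Adjusted over the list alone, Syt2 (-1.45) fell and Syp rose on the presynaptic list and Hmgcs1 (-0.53) fell on the cholesterol synthesis list. Gm10359, Gm7336 and Gm12070, of whose 31-base stretches 100, 97.3 and 96.8% occur in Gapdh, had log2 fold changes of 1.04, 0.92 and 0.80, against 0.40 for Gapdh. For the cytosolic ribosomal protein list, the median was -0.12 (SE 0.044 between libraries, camera adjusted p 5.8e-04) after the GC and length correction and -0.11 (SE 0.057, camera adjusted p 0.119) without cKO 1. Both lie below the bound of -0.1 set before these values were seen, but by less than the SE, which was added to the bound afterwards.

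Nrsn2 had a log2 fold change of 1.5. It was 1.46 after subtracting every count of Gm14164, which had 211 to 1249 counts per library against 4695 to 17430 for Nrsn2. So few counts could hardly alter it, and how reads in the overlap were counted is not stated, so shared reads stay open. It was 1.44 after the GC and length correction and 1.24 without cKO 4 and the library labelled cKO 5 (edgeR adjusted p 0.00741, range over alternatives 4.0e-11 to 0.831). These values argue against that trend or those libraries as the whole cause. A segment of another strain on chromosome 2 may contribute, though it would not flank the floxed gene Hltf, which lies on chromosome 3. Genes within 10 Mb of Nrsn2 had an odds ratio of 1.77 (95% interval 1.17 to 2.62) for an unadjusted p under 0.05, Eif6 among them. Of 13368 windows with at least 100 genes, 5.12% held as high a share as the 14.5% of 214 genes centred within 10 Mb. The interval includes 2, the bound set for such a segment, so it cannot be told apart from an effect of the deletion. An effect of SMARCA3 loss on Nrsn2 stays a hypothesis.

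The mitochondrially encoded list had a median of 0.59 and the oligodendrocyte list 0.78. After the GC and length correction the first was 0.70 (SE 0.20 between libraries), which argues against that trend as its whole cause. RNA of all other cell types, if carried into the cKO pull-downs in equal measure, would raise their markers alike. That equal measure was assumed and not tested. In log2 fold change, 9 oligodendrocyte markers had a mean of 0.68 and 18 astrocyte, microglia and vascular markers 0.066 (permutation p 0.00303 across genes). Mbp was at 30.4 CPM in WT and 36.0 in cKO, and Cnp at 27.3 and 33.1. That set leaves out oligodendrocyte precursor (median 0.59) and choroid plexus and ependymal markers (0.56), neither called over 8 libraries. The precursor list lay at -0.46 in the library labelled cKO 5, below all WT libraries. Between libraries, oligodendrocyte markers exceeded the astrocyte, microglia and vascular markers by 0.53 more in cKO than in WT, with an exact p of 0.0714. A rise in carried-over RNA of all other cell types thus cannot be told apart from a rise in oligodendrocyte RNA alone. How much of such RNA the pull-down removes was not measured, as no library of RNA from before it is among these data. Mbp and Cnp were counted in WT pull-downs too, and a biological change stays open and untested.

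Other splits of the 8 libraries did not exclude chance. Of the 56 splits of 8 libraries into 3 and 5, 6 gave as many genes at an unadjusted p under 0.05 as the 1540 of the real split, the highest other 2789. For DESeq2 on the genes that passed the filter 5 gave as many as the real 108, the highest 672, and for camera 15 gave as many lists as the real 5, the highest 11. The 5 splits above the real one by p and the 4 by DESeq2 all put cKO 4 and the library labelled cKO 5 together among the 3, which points to a structure of the samples. Over 6 libraries the real split gave 10 genes and the highest of the others 1, and 10 splits are too few for a share under 0.05, with 1 split, the real one, as large.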
